A study of Mus musculus with 12 samples.

How the data were processed

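RNA was measured by bulk sequencing in 12 mouse libraries, 3 for each of 4 groups of plasmacytoid dendritic cells (pDCs): pDCs of bone marrow (BM), pDCs of spleen, and pDCs grown from IL7R-positive lymphoid progenitors (IL7R LP-derived) or from common dendritic progenitors (CDP-derived). Per the labels' protocols, total RNA was extracted with the Ambion RNAqueous-Micro kit, cDNA was made with the SMART-Seq v4 kit, a full-length method for low inputs, and libraries were made with Nextera XT. The labels call the libraries of a group biological replicates and do not say that they came from separate animals or cultures, so p-values measure the spread between these libraries. Each library's group and replicate number were taken from its title.

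The deposited table held raw whole-number counts per gene and library, keyed by Entrez gene identifier, with no normalization by the authors that the values show. The submitters' processing notes name STAR, with no version, and the mm10 build; the counting tool, the annotation and the strand setting are not given in the sources used here. One further column of the deposited table, named as gene length per the file headers, was read and entered no test. The table listed 24454 genes. Symbols and positions (GRCm38.p6, the assembly that mm10 stands for) came from RefSeq for 24374 identifiers, and symbols came from GENCODE for 7 more. The remaining 73 identifiers had no name and held 0.270% to 0.658% of a library's counts. No mitochondrial gene was listed. Reads of overlapping antisense genes cannot be told apart here. The near-identical globin genes had counts that lay within 2% of each other over the 12 libraries (Hba-a1 66669 and Hba-a2 66268, Hbb-bs 26518 and Hbb-b1 26516, Hbb-bt 14960 and Hbb-b2 14960), so the value of each single globin gene is uncertain.

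Depth was 28450133 to 33448343 counts per library. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. Where all libraries of a group had no count, a fold is given against a floor of 3 counts over the group and is a lower bound. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 37.2 to 197 over the pairs within groups, and all 12 libraries were kept.

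Differences between groups were tested on the deposited counts with edgeR 4.0.16 (R 4.3.3): TMM normalization, the filterByExpr filter, 1 fit of all 12 libraries with the group as the only term, and the quasi-likelihood F test with Benjamini-Hochberg adjustment over the 13042 genes past the filter. The common dispersion was 0.0838. A gene was called at an adjusted p under 0.05. Levels are given as CPM (counts per 1e6 counts of the TMM-scaled library), mean ± SD of 3 libraries, and log2 fold changes are those of edgeR's fit. There were 6 comparisons.

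In addition, 18 gene lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with the preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The lists were pDC identity, conventional dendritic cell (cDC) identity, MHC class II presentation and co-stimulation, lymphoid progenitor, B cell markers, T and NK cell markers, monocyte and macrophage markers, neutrophil and granule markers, erythroid and megakaryocyte markers, plasma cell markers, interferon-stimulated genes, TLR7/9 sensing and interferon production, cell cycle, sterol biosynthesis, glycolysis and hypoxia, immediate early and stress genes, chemokine receptors and homing, and cytotoxicity and effector molecules. They hold 6 to 36 tested genes each. Camera asks whether a list moved relative to the other genes. The alternatives were camera with an estimated correlation and fry, whose directional p asks whether a list's genes moved, on balance, 1 way. For each list the count of called members is also given adjusted over the list alone.

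The distance of a cultured library to a tissue was the root mean square difference of log2 CPM over the 13042 genes to the mean of that tissue's 3 libraries. The distances of the 3 CDP-derived and the 3 IL7R LP-derived libraries were compared with an exact two-sided permutation test, for which 0.1 is the smallest p that 3 against 3 can give.

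The groups, the tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. For the 4 comparisons of CDP-derived with IL7R LP-derived, splenic with BM, and each cultured group with BM, the rule takes the 8 called genes with the largest fold change in each direction that had separate CPM ranges and a mean of at least 10 CPM over the 6 libraries, leaving out predicted genes, antigen receptor segments and mitochondrial genes. It adds 22 fixed genes (Siglech, Bst2, Tcf4, Spib, Irf8, Zbtb46, Id2, Itgax, Il7r, Rag1, Dntt, Ly6d, Ccr9, Ly6c2, H2-Aa, Cd74, Ciita, Cd86, Tlr7, Tlr9, Irf7 and Csf1r) for every comparison and up to 4 members of each described list, those with the smallest adjusted p. For the comparisons of cultured with splenic pDCs the 8 genes per direction were taken in the same way, which the rule did not foresee. Where another gene is named, the text says that it was chosen after its values were seen.

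The alternatives were DESeq2 size factors, total counts alone, no filter on low counts, a stricter filter (5 CPM in 3 libraries), the DESeq2 1.42.0 Wald test, limma-voom with quality weights, a fit of only the 6 libraries compared, the replicate number as a block, an absolute log2 fold change of at least 1, an adjusted p under 0.01, leaving out ribosomal protein and antigen receptor genes, and leaving out each library in turn. For the lists they included a prior count of 0.5, and for the distances a prior count of 0.5, Spearman correlation and the 500 most variable genes. With 1 library left out the low-count filter was run anew and 13288 to 13325 genes were tested, so a list could hold other members there. The replicate numbers were checked for pairing: the deviations of same-numbered BM and splenic libraries from their group means correlated across genes at 0.435, 0.572 and 0.271, all over the limit of 0.1 fixed for this check, and no other comparison had every pair over it. BM and splenic libraries of 1 number were therefore treated as paired in an alternative. Genes are not independent replicates in these correlations, and no label says what the numbers mark.

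Each test was run on simulated data first. Counts were drawn from each gene's mean and dispersion over all 12 libraries and from their library sizes, with changes planted in the CDP-derived libraries. With 12875 genes tested between CDP-derived and IL7R LP-derived libraries, edgeR called 22 of 95 genes changed 2-fold. It called 77 of 100 genes changed 4-fold, with 8 false calls in all. The DESeq2 Wald test called 42 and 83 with 38 false calls, and limma-voom called 20 and 74 with 9 false calls. Some results for single genes are not reported here.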

Results

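Bulk RNA-seq was available for 4 groups of C57BL/6 mouse plasmacytoid dendritic cells (pDCs), the dendritic cells specialised in making type I interferon, with 3 libraries in each group. Mature pDCs had been taken from bone marrow (BM) and from spleen. The cultured groups were pDCs sorted as BST2 and SiglecH positive after progenitors had grown for 4 days with 100 ng/ml FLT3L, the cytokine that drives dendritic cell development. These progenitors were IL7R-positive lymphoid progenitors (IL7R LP) or common dendritic progenitors (CDP), so the series asks whether pDCs of different origin differ. The libraries held 28450133 to 33448343 counts and 14301 to 15960 genes with a count. The 10 most abundant genes took 6.14% to 9.20% of a library, and ribosomal protein genes took 0.284% to 0.637%. Globin transcripts of red cells took 0.172% to 0.275% of the counts in BM libraries and 0.00624% to 0.00707% in splenic libraries.

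The first principal component held 51.1% of the variance and separated the 6 cultured libraries (45.0 to 76.0) from the 6 tissue libraries (-72.2 to -41.8). On the second, with 13.7%, BM and IL7R LP-derived libraries lay at 22.4 to 40.7 and splenic and CDP-derived libraries at -43.5 to -8.81. Adjusted p-values of single genes below are from edgeR's quasi-likelihood test and those of gene lists from limma's camera with its preset correlation unless another is named, all with Benjamini-Hochberg adjustment. Values are means ± SD of 3 libraries, and positions are in GRCm38.p6.

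**Figure D1:**
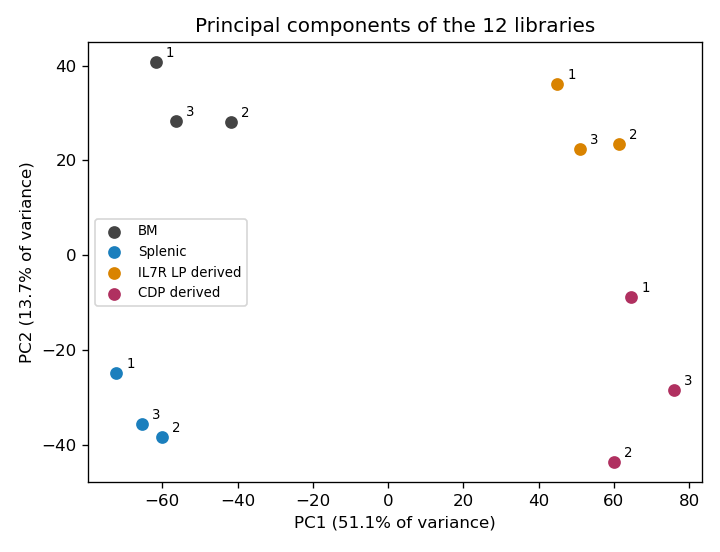
First (x axis, 51.1% of variance) and second (y axis, 13.7%) principal components of log2 CPM, each point 1 library with its replicate number, coloured by group. Cultured libraries lie at 45.0 to 76.0 on the first component and tissue libraries at -72.2 to -41.8.

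The comparison of CDP-derived with IL7R LP-derived pDCs asks what the progenitor leaves in cells grown and sorted in the same way. As lists, monocyte genes were called higher in CDP-derived pDCs, with 5 of 17 members up, and B cell genes lower, with 2 of 9 down (adjusted p = 0.0324 and 0.0378 with an estimated correlation). The cDC list, with 4 of 24 members up and 1 down, was called higher with the preset correlation. With an estimated correlation it was not (adjusted p = 0.0721), and by fry it was (adjusted p = 0.00789). Zbtb46, the transcription factor that marks the cDC lineage, was at 10.4 ± 6.06 CPM in CDP-derived and 0.131 ± 0.0924 CPM in IL7R LP-derived pDCs (n = 3 each). Cd79a, a signalling chain of the B cell receptor, was at 0.337 ± 0.172 against 3.53 ± 1.29 CPM. The markers used for the sort did not pass the test. Siglech, a pDC surface lectin, was at 4289 ± 843 against 4665 ± 723 CPM (log2 fold change -0.12, adjusted p = 0.808). Bst2, the tetherin gene, was at 768 ± 76.1 against 871 ± 109 CPM (log2 fold change -0.18, adjusted p = 0.632). Tcf4, the transcription factor that maintains the pDC fate, had a log2 fold change of -0.08 (adjusted p = 0.836).

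Of 13042 genes tested, 176 rose and 124 fell in CDP-derived relative to IL7R LP-derived pDCs. All 300 had separate ranges in the 3 and 3 libraries. Chance gives these for 10% of genes not chosen by a test, but these genes were chosen on the same libraries, so the ranges add no support. Of the 300, 269 changed at least 2-fold. The count was 176 without IL7R LP-derived replicate 1, 179 without IL7R LP-derived replicate 3 and 172 without CDP-derived replicate 3. Without IL7R LP-derived replicate 2 there were 98 higher genes, and without CDP-derived replicate 2 there were 72 lower genes.

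Among called genes with a mean of at least 10 CPM, the largest rises included Spint1, which encodes the serine protease inhibitor HAI-1 (Entrez 20732, chromosome 2, 119237360 to 119249535), at 41.8 ± 11.0 against 1.34 ± 0.507 CPM (log2 fold change 4.96, SE 0.37, adjusted p = 2.73e-05). Alox5, the 5-lipoxygenase of leukotriene synthesis (Entrez 11689, chromosome 6, 116410071 to 116461178), was at 60.9 ± 8.05 against 2.48 ± 0.662 CPM (log2 fold change 4.62, SE 0.45, adjusted p = 1.68e-04). Cysltr1, a receptor for cysteinyl leukotrienes, rose as well (log2 fold change 2.89, adjusted p = 0.00608), as did Tnfsf9, the ligand of the co-stimulatory receptor 4-1BB (3.11, adjusted p = 1.68e-04). The largest falls at such levels included Padi4, which converts arginine to citrulline in histones (Entrez 18602, chromosome 4, 140745508 to 140774239), at 5.69 ± 0.962 against 28.9 ± 5.15 CPM (log2 fold change -2.34, SE 0.27, adjusted p = 6.62e-04). Abcg3, an ABC transporter gene, was at 7.65 ± 1.80 against 37.8 ± 10.3 CPM (-2.30, adjusted p = 3.02e-04). The interferon-induced GTPase gene Gbp6 fell as well (-3.76, adjusted p = 0.00376), and without IL7R LP-derived replicate 3 its log2 fold change was -2.56 (adjusted p = 0.00123).

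**Figure D2:**
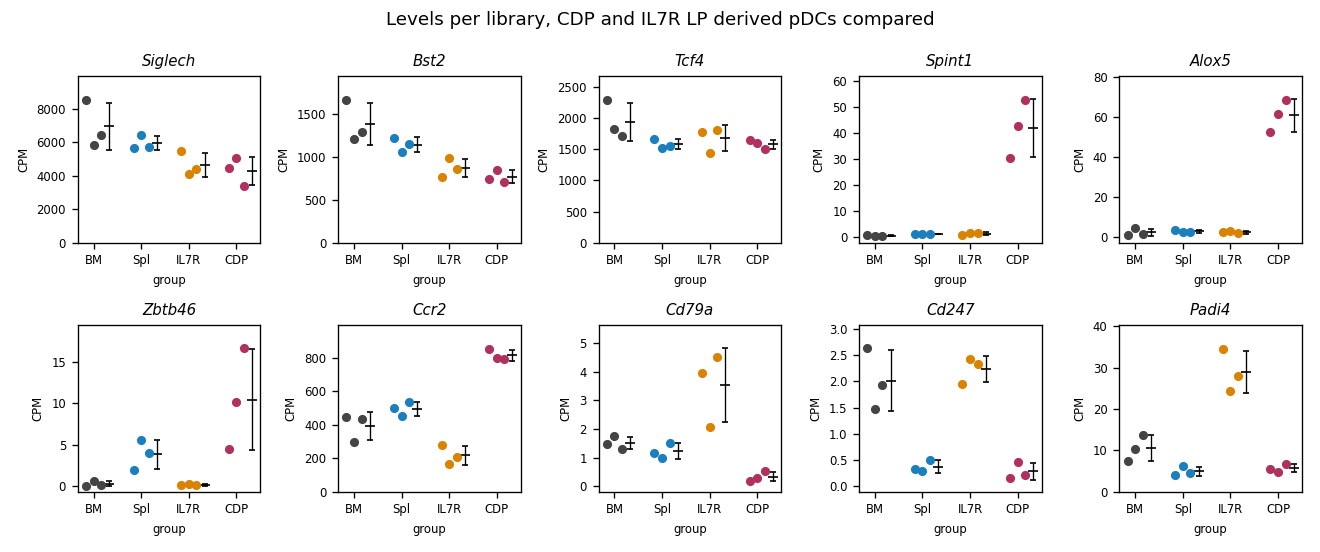
CPM (y axis) of 10 genes in the 4 groups (x axis), with 1 point per library and a black bar for the mean ± SD of 3 libraries. Siglech, Bst2 and Tcf4 overlap between CDP-derived and IL7R LP-derived libraries, whereas Spint1 stands at 41.8 against 1.34 CPM and Padi4 at 5.69 against 28.9 CPM.

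In the cDC identity list 4 of 24 tested members rose and 1 fell (4 and 1 adjusted over the list alone). The list adjusted p was 0.00474, and adjusted p = 0.0721 with an estimated correlation. Zbtb46 (Entrez 72147, chromosome 2, 181371009 to 181493262) had a log2 fold change of 6.26 (SE 0.85, adjusted p = 0.00165; 6.99 without IL7R LP-derived replicate 2). The other risers were the transcription factor gene Klf4 (12.5 ± 5.02 against 1.10 ± 0.537 CPM), the C-type lectin gene Cd209a (310 ± 73.7 against 111 ± 12.6 CPM) and Clec9a, the dead-cell receptor gene of type 1 cDCs (52.3 ± 20.1 against 18.0 ± 3.05 CPM). Cd209a was higher still in BM pDCs, at 772 ± 196 CPM. The faller was Mgl2, a galactose-binding lectin gene chosen after its values were seen (log2 fold change -0.94, adjusted p = 0.0478). In all 0 members fell without IL7R LP-derived replicate 1 or 3 or any 1 CDP-derived library. Id2, a regulator that cDCs need and pDCs keep low, was at 36.7 ± 4.93 against 36.0 ± 7.68 CPM (adjusted p = 0.972). The monocyte and macrophage list was called higher, with 5 of 17 members up (5 adjusted over the list alone). Its mean log2 fold change was 1.04 (adjusted p = 1.28e-04, and adjusted p = 0.0324 with an estimated correlation). Its risers included the lysozyme gene Lyz2 (6.04 ± 1.98 against 0.181 ± 0.135 CPM), the endotoxin co-receptor Cd14 (5.82 ± 1.38 against 0.205 ± 0.0883 CPM) and Ms4a6c (152 ± 69.8 against 23.6 ± 9.01 CPM). In all 3 members were called without IL7R LP-derived replicate 2 or 3. In the MHC class II list 3 of 22 members rose (8 up and 1 down adjusted over the list alone). The mean log2 fold change of its members was 0.62 (adjusted p = 1.34e-06, and adjusted p = 0.146 with an estimated correlation). The lysosomal thiol reductase gene Ifi30 (log2 fold change 1.90, adjusted p = 0.00192) was the 1 member still called without IL7R LP-derived replicate 1, 2 or 3 or CDP-derived replicate 2 or 3.

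In the B cell list 2 of 9 tested members fell in CDP-derived pDCs (3 adjusted over the list alone), and 1 fell without IL7R LP-derived replicate 1 or 2 or CDP-derived replicate 3. The list had a mean log2 fold change of -0.99 (adjusted p = 6.37e-04, and adjusted p = 0.0378 with an estimated correlation). Cd79a (Entrez 12518, chromosome 7, 24897497 to 24901858) had a log2 fold change of -3.37 (SE 0.45, adjusted p = 0.00150). The B cell kinase Blk, at 70.6 ± 18.4 against 151 ± 18.6 CPM (adjusted p = 0.0139), was not called without IL7R LP-derived replicate 1 or 2 or CDP-derived replicate 3 (adjusted p = 0.0637, 0.0558 and 0.0598). Of the lymphoid progenitor list 3 of 16 members fell and 1 rose (list adjusted p = 0.0673; 0.0351 without CDP-derived replicate 3). Dntt, the terminal transferase of antigen receptor assembly, was at 150 ± 36.7 against 317 ± 68.5 CPM (adjusted p = 0.0130). Its adjusted p was 0.0664, 0.0585 and 0.0760 without IL7R LP-derived replicate 1, CDP-derived replicate 2 or CDP-derived replicate 3. Il2rg, the shared cytokine receptor chain gene, was the riser at 327 ± 81.9 against 121 ± 33.1 CPM. The T cell receptor chain gene Cd247 fell from 2.24 ± 0.248 to 0.280 ± 0.159 CPM (log2 fold change -2.97, adjusted p = 0.00363) in a T and NK cell list that was not called (adjusted p = 0.0673; 0.0462 without IL7R LP-derived replicate 2).

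Among homing receptors, Ccr2, which guides cells out of bone marrow (Entrez 12772), rose from 216 ± 56.1 to 815 ± 32.0 CPM (log2 fold change 1.91, SE 0.20, adjusted p = 3.10e-04). The inflammatory chemokine receptor gene Ccr1 rose from 3.31 ± 0.752 to 42.9 ± 20.5 CPM and Ccr10, a skin homing receptor gene, fell from 3.15 ± 1.37 to 0.342 ± 0.0967 CPM. The list of 24 chemokine receptor and trafficking genes was not called (adjusted p = 0.952). In the pDC identity list Cd209d (60.0 ± 20.4 against 9.25 ± 2.11 CPM) and Ly6c2 (258 ± 57.9 against 90.5 ± 30.4 CPM) rose and Klk1 fell among 34 members (2 and 5 adjusted over the list alone; list adjusted p = 0.270). Klk1 was not called without replicate 1 or 3 of either group (adjusted p = 0.0885 to 0.146). The glycolysis and hypoxia list was called higher with 0 of 25 members called by edgeR (0 adjusted over the list alone). The list as a whole had an adjusted p of 3.07e-05, and adjusted p = 0.514 with an estimated correlation. Its median in CDP-derived replicate 2, 57.0 CPM, lay within the 49.6 to 77.7 CPM of the IL7R LP-derived libraries, whereas replicates 1 and 3 had 161 and 157 CPM, and the mean log2 fold change of 0.65 became 1.13 without CDP-derived replicate 2 and 0.36 without IL7R LP-derived replicate 2. The hexokinase gene Hk2 was at 23.8 ± 5.47 against 8.31 ± 4.31 CPM (adjusted p = 0.0812). The cell cycle list was called lower with 0 of 36 members called (0 adjusted over the list alone; mean log2 fold change -0.25, adjusted p = 0.0146, and adjusted p = 0.633 with an estimated correlation). It was not called without IL7R LP-derived replicate 2 or CDP-derived replicate 2 (adjusted p = 0.458 and 0.0951). Interferon-stimulated genes were called lower as a list, with 0 of 35 members called by edgeR and 17 adjusted over the list alone (mean log2 fold change -0.79, adjusted p = 8.37e-04, and adjusted p = 0.633 with an estimated correlation). Without IL7R LP-derived replicate 3, whose median over the list was 34.5 CPM against 3.88 and 2.27 CPM in replicates 1 and 2, the mean log2 fold change was 0.22 (adjusted p = 0.231). Cytotoxicity and effector genes were not called as a list (adjusted p = 0.0530), but were without IL7R LP-derived replicate 1 or 2 or CDP-derived replicate 2 (0.0107, 0.0296 and 0.0205). Neither were immediate early and stress genes (0.0631) or sterol biosynthesis (0.215), which were called without CDP-derived replicate 2 (0.0411 and 0.00708). Plasma cell (0.200), neutrophil and granule (0.215), erythroid and megakaryocyte (0.803) and TLR7/9 sensing lists (0.952) were not called. The chemokine receptor and TLR7/9 sensing lists had means of 0.05 and medians below 0.

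Splenic and BM pDCs were compared to ask how mature pDCs of different tissues differ. The cell cycle list was called lower in spleen, with 26 of 36 members down (adjusted p = 0.00609 with an estimated correlation). The MHC class II list, with 4 of 22 members up, was called higher with the preset correlation. With an estimated correlation it was not (adjusted p = 0.0771), and by fry it was (adjusted p = 0.00258). Il9r, the interleukin 9 receptor gene, was at 31.8 ± 7.78 CPM in splenic and 0.697 ± 0.358 CPM in BM pDCs (n = 3 each). Rrm2, the ribonucleotide reductase subunit needed for DNA synthesis, was at 4.68 ± 1.02 against 76.1 ± 2.41 CPM. Genes of granulocytes and red cells were also higher in the BM libraries: Ltf, the neutrophil granule gene for lactoferrin, was at 70.6 ± 50.0 CPM there and had 0 counts in spleen, at least 2033-fold lower. Its fitted log2 fold change of -14.09 (-13.44 without BM replicate 2) rests on those 0 counts, so only the bound can be read.

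Of the 13042 genes, 107 rose and 215 fell in spleen relative to BM, 295 of them at least 2-fold. All of these called genes had separate ranges (10% by chance for genes not chosen by a test). The number of higher genes was 63 without BM replicate 1, 68 without splenic replicate 1 and 62 without splenic replicate 3. With the replicate number as a block in a fit of only these 6 libraries, an alternative chosen after seeing the data, 817 genes were called, 353 higher and 464 lower, and 309 of the 322 were among them. In that fit 11 members of the MHC class II list rose and 1 fell, 15 of the immediate early and stress list rose, 5 of the monocyte list rose and 2 fell, 4 of the cDC list rose, and 1 of the pDC identity list rose and 3 fell. There camera called 9 of 18 lists with the preset correlation. With an estimated correlation it called 0 (lowest adjusted p = 0.359), the cell cycle list included, in a fit of fewer libraries.

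Il9r (Entrez 16199, chromosome 11, 32187544 to 32205283) had the largest rise among called genes with a mean of at least 10 CPM (log2 fold change 5.51, SE 0.51, adjusted p = 3.56e-05). Sema4a, a semaphorin that acts on T cells (Entrez 20351, chromosome 3, 88435959 to 88461182), was at 83.3 ± 2.54 against 9.45 ± 2.51 CPM (log2 fold change 3.14, SE 0.20, adjusted p = 2.61e-06). Plbd1, a lysosomal phospholipase-like gene, was at 153 ± 25.8 against 13.3 ± 6.44 CPM (adjusted p = 1.30e-04), and the fractalkine receptor gene Cx3cr1 was at 34.3 ± 4.95 against 5.95 ± 3.10 CPM (adjusted p = 0.00111). The lymphotoxin beta gene Ltb rose from 10.5 ± 6.76 to 69.9 ± 18.1 CPM (log2 fold change 2.74, adjusted p = 0.00479; 3.38 without BM replicate 2). Siglech (5941 ± 422 against 6953 ± 1393 CPM, adjusted p = 0.804), Bst2 (adjusted p = 0.629), Tcf4 (adjusted p = 0.533) and Irf8, a transcription factor of dendritic cells (adjusted p = 0.956), did not pass the test.

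**Figure D3:**
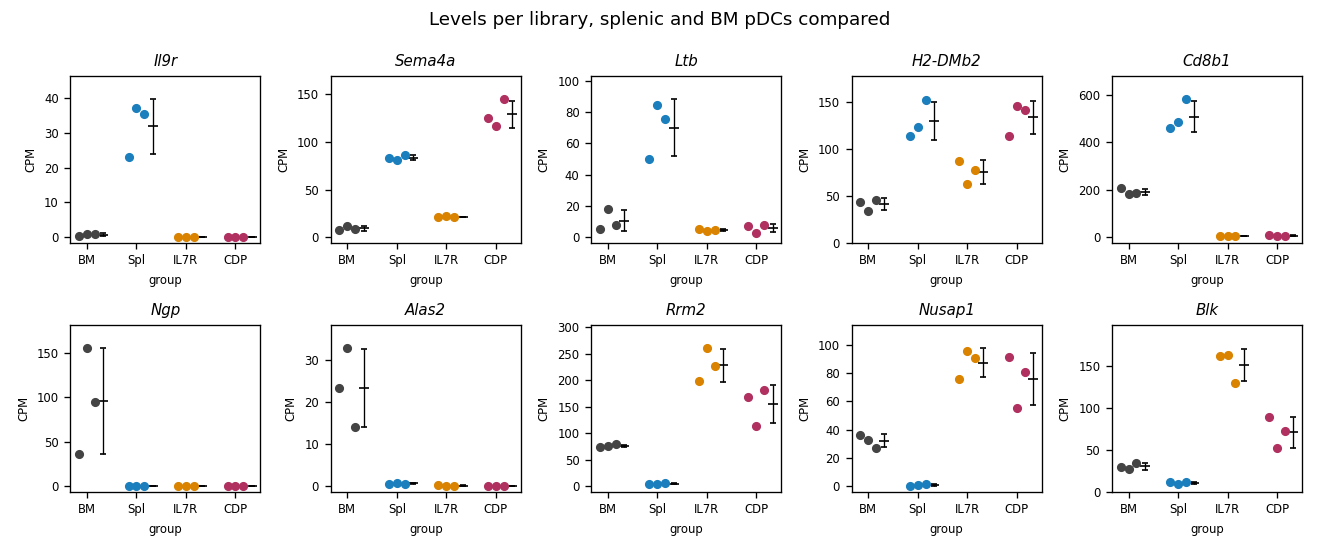
CPM (y axis) of 10 genes in the 4 groups (x axis), with 1 point per library and a black bar for the mean ± SD of 3 libraries. Il9r stands at 31.8 CPM in spleen against 0.697 CPM in BM, and Rrm2 at 4.68 CPM in spleen against 76.1 CPM in BM.

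In the cell cycle list 26 of 36 members fell in spleen and 0 rose (33 fell adjusted over the list alone). Its mean log2 fold change was -2.44 (adjusted p = 5.28e-58, and adjusted p = 0.00609 with an estimated correlation). Rrm2 (Entrez 20135, chromosome 12, 24708254 to 24714146) had a log2 fold change of -4.02 (SE 0.23, adjusted p = 1.89e-06). The kinetochore motor gene Cenpe was at 1.19 ± 0.0951 against 12.4 ± 0.536 CPM and the mitotic cyclin gene Ccnb2 had a log2 fold change of -4.51 (adjusted p = 3.72e-06). In the neutrophil and granule list 11 of 13 members fell (13 adjusted over the list alone; adjusted p = 1.56e-38, and adjusted p = 0.0111 with an estimated correlation). S100a8, a calcium-binding protein gene of neutrophils, was at 33.9 ± 18.9 CPM in BM (log2 fold change -8.84, adjusted p = 3.46e-05; -9.80 without splenic replicate 3). The neutrophil list summed to 116, 563 and 304 CPM in the 3 BM libraries and to 1.65, 1.78 and 3.66 CPM in the splenic ones. In the erythroid and megakaryocyte list 7 of 13 members fell (11 adjusted over the list alone; adjusted p = 8.90e-24, and adjusted p = 0.00541 with an estimated correlation). The heme synthesis gene Alas2 was at 0.653 ± 0.122 against 23.3 ± 9.30 CPM and the alpha globin gene Hba-a1 at 21.4 ± 2.57 against 721 ± 157 CPM.

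In the MHC class II list 4 of 22 members rose (14 up and 1 down adjusted over the list alone). The mean log2 fold change of its members was 0.64 (adjusted p = 5.62e-08, and adjusted p = 0.0771 with an estimated correlation). H2-DMb2, part of the peptide exchanger for class II, was at 130 ± 19.9 against 41.2 ± 6.38 CPM (adjusted p = 2.35e-04) and the class II beta chain gene H2-Ab1 at 6549 ± 761 against 3385 ± 517 CPM (log2 fold change 0.95, adjusted p = 0.00195). Without splenic replicate 2 or BM replicate 3, 2 members rose. In the immediate early and stress list 3 of 27 members rose (8 adjusted over the list alone). Its mean log2 fold change was 0.90 (adjusted p = 2.27e-07, and adjusted p = 0.0454 with an estimated correlation). Zfp36, which encodes an mRNA-destabilising protein induced by stress, was at 786 ± 92.3 against 419 ± 87.8 CPM (adjusted p = 0.0219). Without replicate 1 of either tissue, BM replicate 2 or splenic replicate 3, 0 members were called and the adjusted p of Zfp36 was 0.0825 to 0.111. Median levels of this list differed between libraries of 1 tissue: 13.9, 29.0 and 29.6 CPM in BM and 33.2, 54.9 and 42.3 CPM in spleen.

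The monocyte and macrophage list was called higher (mean log2 fold change 0.26, adjusted p = 0.00221, and adjusted p = 0.0298 with an estimated correlation), with 3 of 17 members up and 1 down (3 and 2 adjusted over the list alone). The risers were Cx3cr1, the endotoxin co-receptor gene Cd14 and Csf1r, the macrophage growth factor receptor gene. Csf1r was not called without replicate 1 of either tissue, splenic replicate 2 or BM replicate 3 (adjusted p = 0.0687 to 0.112), nor Cd14 without replicate 1 or 3 of spleen or 2 or 3 of BM (0.127 to 0.164). Lyz2 was the faller, at 14.8 ± 6.87 against 95.3 ± 48.1 CPM (adjusted p = 0.00795). The pDC identity list was called lower by a mean log2 fold change of -0.11 (adjusted p = 0.0247, and adjusted p = 0.316 with an estimated correlation). It was not called without BM replicate 1, splenic replicate 1 or splenic replicate 2 (adjusted p = 0.262, 0.111 and 0.0620). Its 1 called member of 34 (1 adjusted over the list alone), Cd8a, rose from 124 ± 12.9 to 275 ± 20.2 CPM (adjusted p = 0.0190), and was not called without replicate 2 or 3 of either tissue (0.0639 to 0.0811). Cd8b1, the partner chain gene of the CD8 co-receptor, rose as well (log2 fold change 1.41, SE 0.21, adjusted p = 0.00154). The B cell list was called lower (mean log2 fold change -0.34, adjusted p = 0.0457, and adjusted p = 0.109 with an estimated correlation) but not after leaving out any 1 of the 6 libraries (mean -0.19 to 0.13, adjusted p = 0.171 to 0.819). The left-out fits also tested more genes, so this loss cannot be laid to the missing library alone. Of the list's 9 members Blk fell (log2 fold change -1.47, adjusted p = 0.00143), and 2 fell adjusted over the list alone.

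Zbtb46 was at 3.81 ± 1.81 CPM in spleen and 0.269 ± 0.297 CPM in BM (log2 fold change 3.81, adjusted p = 0.0167). This call was lost without splenic replicate 2 or BM replicate 3 (adjusted p = 0.0584 and 0.0805), and the log2 fold change was 5.16 without BM replicate 2. The cDC list was not called (adjusted p = 0.256), and its other riser, Klf4, was at 16.7 ± 4.16 against 2.09 ± 0.602 CPM (adjusted p = 9.75e-04). The survival gene Bcl2 fell from 10.8 ± 3.09 to 2.81 ± 0.333 CPM (adjusted p = 2.88e-04) in a lymphoid progenitor list that was not called (adjusted p = 0.0818; 0.0372 without BM replicate 3). The other lists were not called either: T and NK cell and chemokine receptor lists (0.146 each), interferon-stimulated (0.211) and glycolysis lists (0.211), cytotoxicity (0.479), plasma cell (0.561), TLR7/9 sensing (0.658) and sterol lists (0.712; 0.0354 without BM replicate 1). The cytotoxicity and TLR7/9 lists had means below 0 and medians of 0.05. In the fit of the 6 libraries with the replicate number as a block, interferon-stimulated genes were called lower in spleen as a list (mean log2 fold change -0.36, adjusted p = 8.55e-05, and adjusted p = 0.374 with an estimated correlation). There 7 of 35 members fell, among them Ifit2 (-0.96, adjusted p = 9.33e-04), Slfn5 (-1.08, adjusted p = 0.00697) and Rtp4 (-1.74, adjusted p = 0.0108).

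IL7R LP-derived pDCs were compared with BM pDCs to see how far cells grown from lymphoid progenitors differ from those in the marrow. The cell cycle list was called higher in the cultured cells (29 of 36 members up), and the monocyte (10 of 17 down and 2 up) and pDC identity lists (12 of 34 down) lower. With an estimated correlation their adjusted p was 0.0497, 0.00368 and 0.0397. Scin, the actin-severing scinderin (Entrez 20259, chromosome 12, 40059769 to 40134228), was at 45.0 ± 4.08 CPM (n = 3) in the cultured cells and had no count in BM, a rise of at least 1345-fold. Klk1, a kallikrein protease of the pDC list (Entrez 16612), fell from 731 ± 122 to 30.1 ± 7.53 CPM (log2 fold change -4.60, SE 0.26, adjusted p = 3.55e-07). Bst2 fell from 1383 ± 244 to 871 ± 109 CPM (log2 fold change -0.67, adjusted p = 0.0130; 0.0587 without BM replicate 1 and 0.0574 without IL7R LP-derived replicate 1). Siglech was at 4665 ± 723 against 6953 ± 1393 CPM (-0.58, adjusted p = 0.0581; 0.0462 without IL7R LP-derived replicate 1 and 0.0306 without BM replicate 2).

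In this comparison 805 genes rose and 889 fell, 1303 of them at least 2-fold. Of these called genes, 1685 had separate ranges (10% by chance for genes not chosen by a test). With scaling by total counts alone, which shifts the median log2 fold change of all genes by 0.11, 1046 rose and 731 fell. The number of higher genes was 536 without IL7R LP-derived replicate 2 and 1211 without BM replicate 2.

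Among other large rises, Slc35d3, a transporter-family gene, was at 19.2 ± 2.53 against 1.16 ± 0.437 CPM (log2 fold change 4.04, SE 0.36, adjusted p = 1.73e-05). Cnn3, the actin-binding calponin 3 gene, was at 143 ± 20.9 against 12.5 ± 6.13 CPM (3.51, SE 0.32, adjusted p = 2.24e-05). Hbb-bs, a beta globin gene at 287 ± 72.4 CPM in BM, had no count in IL7R LP-derived libraries and was at least 9341-fold lower. Erythroid (10 of 13 down, 11 adjusted over the list alone) and neutrophil (12 of 13 down, 12 adjusted over the list alone) lists were called lower. Their adjusted p was 4.20e-19 and 3.99e-19, and 0.00574 and 0.0463 with an estimated correlation.

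In the cell cycle list 29 of 36 members rose (32 adjusted over the list alone). The mean log2 fold change of its members was 1.36 (adjusted p = 3.99e-19, and adjusted p = 0.0497 with an estimated correlation). Cenpe was at 51.1 ± 10.1 against 12.4 ± 0.536 CPM and Rrm2 at 228 ± 31.1 against 76.1 ± 2.41 CPM. In the glycolysis and hypoxia list 9 of 25 members rose (18 adjusted over the list alone; 5 without BM replicate 1 or 3 or IL7R LP-derived replicate 3). The list adjusted p was 3.09e-06, and adjusted p = 0.334 with an estimated correlation. The glycolytic enzyme genes Tpi1 (335 ± 146 against 56.7 ± 12.5 CPM) and Eno1 (390 ± 99.4 against 141 ± 15.3 CPM) were among them. The B cell list was called higher with 3 of 9 members up (5 up and 3 down adjusted over the list alone). Its adjusted p was 0.0314, adjusted p = 0.0863 with an estimated correlation, 0.0501 with a replicate block, and 0.138 to 0.246 after leaving out any 1 of the 6 libraries. The left-out fits also tested more genes, so their loss of the call cannot be laid to the missing library alone. The risers of the B cell list were Blk (log2 fold change 2.33, SE 0.22, adjusted p = 2.24e-05), the adaptor gene Bank1 and the inhibitory receptor gene Cd22. The survival gene Bcl2 rose from 10.8 ± 3.09 to 81.2 ± 10.2 CPM (log2 fold change 2.91, adjusted p = 8.21e-06) in a lymphoid progenitor list that was not called (adjusted p = 0.0736; 0.0355 and 0.0308 without replicate 2 of BM or of the IL7R LP-derived group). The sterol list was called higher (adjusted p = 0.00170, and adjusted p = 0.344 with an estimated correlation; 0.0634 without BM replicate 2). Of its 24 members 1 was called (0 adjusted over the list alone), Acat2, an early enzyme gene of the pathway, at 143 ± 17.3 against 77.7 ± 22.2 CPM. Acat2 was not called without replicate 1 or 3 of the cultured group or replicate 2 or 3 of BM (adjusted p = 0.0559 to 0.0835).

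In the pDC identity list 12 of 34 members fell and 0 rose (19 fell adjusted over the list alone). Its mean log2 fold change was -0.97 (adjusted p = 1.68e-08, and adjusted p = 0.0397 with an estimated correlation). Besides Klk1 these included the lectin gene Cd209d (9.25 ± 2.11 against 365 ± 115 CPM) and the Ly6 family gene Ly6c2 (90.5 ± 30.4 against 1563 ± 276 CPM). Id2, the cDC regulator, rose from 8.53 ± 1.26 to 36.0 ± 7.68 CPM (adjusted p = 1.21e-04). In the TLR7/9 sensing list 8 of 20 members fell and 1 rose (8 and 1 adjusted over the list alone; 5 fell without IL7R LP-derived replicate 2). The list as a whole had an adjusted p of 0.00291, and 0.0397 with an estimated correlation. Its members included Tlr9, the endosomal DNA receptor gene, at 3.42 ± 0.353 against 11.0 ± 2.60 CPM (adjusted p = 0.00263). In the immediate early and stress list 13 of 27 members fell and 1 rose (18 and 1 adjusted over the list alone; 8 fell without IL7R LP-derived replicate 1 or BM replicate 3). The list adjusted p was 3.04e-06, and adjusted p = 0.0507 with an estimated correlation. Fos, the growth-induced AP-1 subunit gene, was at 3.17 ± 1.20 against 274 ± 152 CPM (adjusted p = 2.22e-05).

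In the interferon-stimulated list 8 of 35 members fell (14 adjusted over the list alone; adjusted p = 1.52e-12, and adjusted p = 0.217 with an estimated correlation). The count was 31 without IL7R LP-derived replicate 3, 2 without IL7R LP-derived replicate 1, 3 without its replicate 2, 5 without BM replicate 2 and 4 without BM replicate 3. Gbp3, an interferon-induced GTPase gene, was at 7.48 ± 0.469 against 17.3 ± 2.10 CPM (adjusted p = 0.00459). Irf7, the regulator of interferon genes, was at 491 ± 313 against 1462 ± 364 CPM (log2 fold change -1.58, adjusted p = 0.00939). Without IL7R LP-derived replicate 3 its log2 fold change was -2.23, and without replicate 2 its adjusted p was 0.0502. In the monocyte list 10 of 17 members fell and 2 rose (12 and 2 adjusted over the list alone; 1 rose without replicate 1 of either group or IL7R LP-derived replicate 2). The list as a whole had an adjusted p of 9.12e-09, and 0.00368 with an estimated correlation, and Lyz2 was at 0.181 ± 0.135 against 95.3 ± 48.1 CPM. The cytotoxicity list was called lower with 6 of 13 members down and 2 up (7 and 2 adjusted over the list alone). Its adjusted p was 0.00516, and adjusted p = 0.0507 with an estimated correlation. Il12a, the p35 chain gene of interleukin 12, was a riser of it (log2 fold change 3.28, adjusted p = 7.17e-05). Cd8b1 of the T and NK cell list fell to 4.54 ± 1.18 CPM (-5.40, SE 0.25, adjusted p = 4.63e-08). The cDC (adjusted p = 0.102; 5 up and 6 down of 24), chemokine receptor (0.379), MHC class II (0.482), T and NK cell (0.820) and plasma cell lists (0.930) were not called. Mean, median and test differed in sign for the last of these and for the T and NK cell and chemokine receptor lists.

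**Figure D4:**
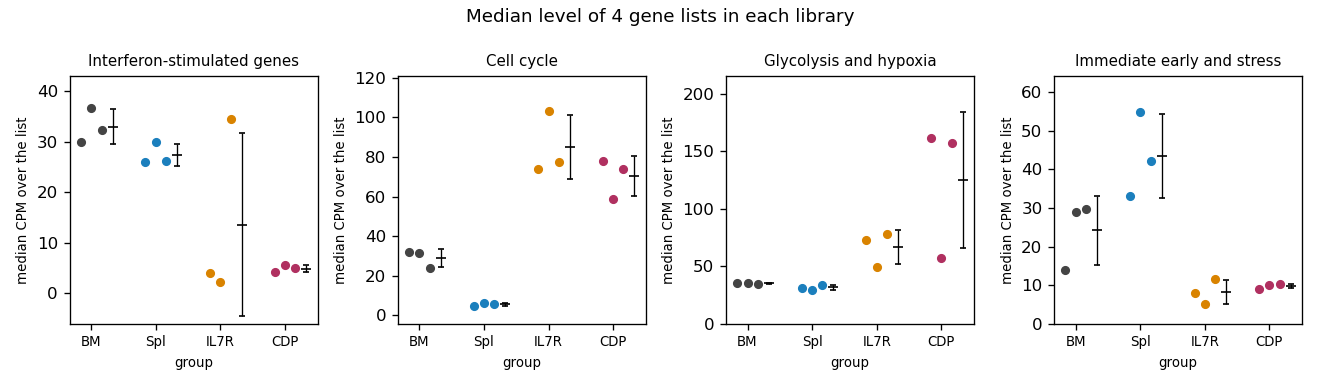
Median CPM (y axis) over the members of 4 gene lists in each library, by group (x axis), with black bars for the mean ± SD of 3 libraries. The cell cycle list lies at 4.80 to 6.13 CPM in spleen, 23.9 to 32.2 in BM and 59.0 to 103 in the cultured groups, and IL7R LP-derived replicate 3 stands at 34.5 CPM in the interferon-stimulated list.

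CDP-derived pDCs were compared with BM pDCs in the same way. The pDC identity list was called lower in the cultured cells, with 20 of 34 members down and 2 up (adjusted p = 0.0490 with an estimated correlation). With the preset correlation, interferon-stimulated genes were called lower (30 of 35 down) and glycolysis (19 of 25 up) and cell cycle genes (23 of 36 up) higher. With an estimated correlation these lists were not called (adjusted p = 0.233, 0.289 and 0.187). By fry they were (adjusted p = 0.00312, 0.00525 and 7.22e-04). Dpep2, a leukotriene-processing dipeptidase gene (Entrez 319446, chromosome 8, 105984945 to 106006026), rose from 1.07 ± 0.263 to 71.8 ± 16.2 CPM (n = 3; log2 fold change 6.07, SE 0.40, adjusted p = 9.07e-07). Bst2 fell from 1383 ± 244 to 768 ± 76.1 CPM (-0.85, adjusted p = 0.00226), as did Siglech from 6953 ± 1393 to 4289 ± 843 CPM (-0.70, adjusted p = 0.0161). The Siglech call was lost without BM replicate 1 or CDP-derived replicate 3 (adjusted p = 0.0660 and 0.0679) and with total-count scaling or a fit of only the 6 libraries (0.0517 and 0.0576).

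In all, 1422 genes rose and 1731 fell, 2149 of them at least 2-fold. Of these called genes, 3095 had separate ranges (10% by chance for genes not chosen by a test). With total-count scaling, which shifts the median by 0.15, 1990 rose and 1319 fell. The number of higher genes was 941 without BM replicate 1 and 917 without CDP-derived replicate 3.

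Scin was at 71.2 ± 20.4 CPM against no count in BM, at least 2129-fold higher, and Spint1 was at 41.8 ± 11.0 against 0.576 ± 0.200 CPM (log2 fold change 6.17, SE 0.40, adjusted p = 8.46e-07). Cysltr1 was at 84.8 ± 12.7 against 0.598 ± 0.441 CPM (7.14; 7.92 without BM replicate 3), and Zbtb46 rose by 5.26 (adjusted p = 6.23e-04; 6.65 without BM replicate 2). The transcription factor gene Spib of the pDC programme fell from 1724 ± 116 to 848 ± 304 CPM (adjusted p = 0.00614). In the pDC identity list 20 of 34 members fell and 2 rose (25 and 2 adjusted over the list alone). The list adjusted p was 1.86e-08, and 0.0490 with an estimated correlation, and Klk1 was at 14.6 ± 2.89 against 731 ± 122 CPM. In the TLR7/9 sensing list 9 of 20 members fell and 4 rose (10 and 4 adjusted over the list alone; adjusted p = 0.0148, and adjusted p = 0.0775 with an estimated correlation). Of the 4, 2 rose without BM replicate 1 or CDP-derived replicate 3 and 1 without BM replicate 3. Tlr7, the RNA receptor gene, was at 140 ± 16.6 against 337 ± 40.2 CPM (adjusted p = 0.00138).

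Of the interferon-stimulated list 30 of 35 members fell (33 adjusted over the list alone). The mean log2 fold change of its members was -3.05 (adjusted p = 1.92e-13, and adjusted p = 0.233 with an estimated correlation), and Stat2, a transcription factor gene of interferon responses, was at 304 ± 71.6 against 780 ± 61.9 CPM. In the glycolysis and hypoxia list 19 of 25 members rose (19 adjusted over the list alone; adjusted p = 1.30e-08, and adjusted p = 0.289 with an estimated correlation). Tpi1, a glycolytic enzyme gene, was at 674 ± 340 against 56.7 ± 12.5 CPM. List medians were 161, 57.0 and 157 CPM in the 3 CDP-derived libraries and 34.9 to 35.7 CPM in BM. In the cell cycle list 23 of 36 members rose (24 adjusted over the list alone; adjusted p = 1.48e-09, and adjusted p = 0.187 with an estimated correlation). Cenpe was at 63.0 ± 6.24 against 12.4 ± 0.536 CPM. In the sterol list 6 of 24 members rose (7 adjusted over the list alone; adjusted p = 0.00121, and adjusted p = 0.412 with an estimated correlation). In all 10 rose without BM replicate 1, 3 without CDP-derived replicate 1 and 2 without CDP-derived replicate 3. In the MHC class II list 8 of 22 members rose and 2 fell (9 and 4 adjusted over the list alone; adjusted p = 0.0238, and adjusted p = 0.420 with an estimated correlation). H2-Ob, a modulator gene of peptide loading, was at 115 ± 14.7 against 19.0 ± 1.86 CPM. The list was not called without BM replicate 2 or CDP-derived replicate 2 (adjusted p = 0.0762 and 0.0783), and its fallers numbered 4 without CDP-derived replicate 2 and 1 without CDP-derived replicate 1 or 3.

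Lists of other cells were called lower as well. Cells carried into the BM sort could give falls in such lists, which these libraries cannot separate from a change within pDCs. Erythroid genes fell in 10 of 13 (11 adjusted over the list alone; adjusted p = 1.92e-13, and 0.0329 with an estimated correlation). Neutrophil genes fell in 12 of 13 (12 down and 1 up adjusted over the list alone; 3.33e-13, and adjusted p = 0.0948 with an estimated correlation). Of monocyte genes 11 of 17 fell and 5 rose (11 and 6 adjusted over the list alone; 0.0141, and adjusted p = 0.0775 with an estimated correlation). Lyz2 fell from 95.3 ± 48.1 to 6.04 ± 1.98 CPM, whereas Csf1r, the macrophage growth factor receptor gene, rose from 6.44 ± 2.25 to 41.7 ± 18.3 CPM. Of immediate early and stress genes 12 of 27 fell and 2 rose (14 and 2 adjusted over the list alone; 8 fell without CDP-derived replicate 1 or BM replicate 3). The list as a whole had an adjusted p of 0.00198, and adjusted p = 0.197 with an estimated correlation. The growth-inhibiting gene Btg2 was at 796 ± 38.9 against 1777 ± 210 CPM. The cytotoxicity list was called lower (8 of 13 down and 2 up, 9 and 2 adjusted over the list alone; adjusted p = 6.52e-04, and 0.0490 with an estimated correlation). Ccl3, an inflammatory chemokine gene, was at 0.636 ± 0.282 against 4.95 ± 1.29 CPM. T and NK cell (adjusted p = 0.276), chemokine receptor (0.533), lymphoid progenitor (0.649), plasma cell (0.656), cDC (0.677; 8 up and 6 down of 24) and B cell lists (0.883) were not called. Mean, median and test differed in sign for these lists except T and NK cell and cDC.

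Relative to splenic pDCs, 36 of 36 cell cycle genes rose in IL7R LP-derived and 33 of 36 in CDP-derived pDCs (list adjusted p = 0.0193 and adjusted p = 0.0517 with an estimated correlation). Pimreg, a mitotic gene (Entrez 109212, chromosome 11, 72042428 to 72047372), was at 40.7 ± 13.4 CPM in IL7R LP-derived, 42.2 ± 3.82 CPM in CDP-derived and 0.0834 ± 0.0447 CPM in splenic pDCs (n = 3 each; log2 fold changes 8.89 and 8.95, adjusted p = 9.12e-08 and 9.10e-08). Cd8b1 fell from 509 ± 63.8 CPM in spleen to 4.54 ± 1.18 CPM in IL7R LP-derived and 6.95 ± 1.59 CPM in CDP-derived pDCs. Dll1, the Notch ligand gene (Entrez 13388), fell from 56.3 ± 10.3 to 0.570 ± 0.170 CPM in CDP-derived pDCs (adjusted p = 1.31e-07). Zbtb46 was lower in IL7R LP-derived pDCs (log2 fold change -4.81, adjusted p = 0.00132; -5.54 without IL7R LP-derived replicate 2), and in CDP-derived pDCs it did not pass the test (1.45, adjusted p = 0.114).

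IL7R LP-derived minus splenic gave 1025 higher and 1143 lower genes, 1635 of them at least 2-fold. Of these called genes, 2159 had separate ranges (10% by chance for genes not chosen by a test). Total-count scaling (median shift 0.13) gave 1264 and 899. CDP-derived minus splenic gave 1416 higher and 1733 lower genes, 2084 at least 2-fold and 3107 with separate ranges. Total-count scaling (median shift 0.17) gave 1960 and 1220, and the fit gave 2095 in all without splenic replicate 1 and 2084 without CDP-derived replicate 3.

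For IL7R LP-derived minus splenic, 12 lists were called. Cell cycle genes rose in 36 of 36 (36 adjusted over the list alone; adjusted p = 3.12e-40, and 0.0193 with an estimated correlation). Monocyte genes fell in 12 of 17 (15 adjusted over the list alone; 3.13e-11, and 0.00125 with an estimated correlation). Immediate early genes fell in 20 of 27 with 1 rise (20 and 2 adjusted over the list alone; 5.50e-09, and 0.0406 with an estimated correlation; 3 rises without splenic replicate 2). Erythroid genes fell in 9 of 13 (9 adjusted over the list alone; 4.35e-08, and 0.0437 with an estimated correlation) and TLR7/9 sensing genes in 7 of 20 with 1 rise (11 and 2 adjusted over the list alone; 0.00681, and 0.0483 with an estimated correlation). Fos stood at 704 ± 165 CPM in spleen and 3.17 ± 1.20 CPM in these cells. In the MHC class II list 10 of 22 members fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 1.43e-04, and adjusted p = 0.152 with an estimated correlation; 5 fell without splenic replicate 3). H2-Ab1 was at 3329 ± 43.6 against 6549 ± 761 CPM. Interferon-stimulated (8 of 35 down, 8 adjusted over the list alone; adjusted p = 2.06e-08, and adjusted p = 0.311 with an estimated correlation) and pDC identity lists (11 of 34 down and 2 up, 12 and 2 adjusted over the list alone; 8.01e-04, and adjusted p = 0.145 with an estimated correlation) were called lower. The count of interferon-stimulated genes was 29 without IL7R LP-derived replicate 3, and 3 to 5 without replicate 1 of either group, IL7R LP-derived replicate 2 or splenic replicate 3. The glycolysis list was called higher (15 of 25 up, 18 adjusted over the list alone; 1.50e-06, and adjusted p = 0.311 with an estimated correlation), with 8 up without replicate 1 or 3 of either group. Sterol (0 of 24 called, 0 adjusted over the list alone; 0.00472, and adjusted p = 0.371 with an estimated correlation) and lymphoid progenitor lists (5 of 16 up and 1 down, 7 and 2 adjusted over the list alone; 0.0103, and adjusted p = 0.145 with an estimated correlation) were called higher. So was the B cell list (4 of 9 up, 5 up and 1 down adjusted over the list alone, adjusted p = 0.00837, and adjusted p = 0.0588 with an estimated correlation), though not without splenic replicate 1 or 3 or any 1 cultured library (0.108 to 0.280). The left-out fits also tested more genes, so this loss cannot be laid to the missing library alone. The cDC list (0.0543; 0.0493 and 0.0469 without IL7R LP-derived replicate 1 or 3) and the cytotoxicity list (0.0590; 0.0154 without IL7R LP-derived replicate 3) were not called, nor were the T and NK cell (0.114), neutrophil (0.577), chemokine receptor (0.874; mean and median above 0, test down) and plasma cell lists (0.988).

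For CDP-derived minus splenic, 10 lists were called with the preset correlation. With an estimated correlation 0 were called by limma's camera, against 7 at an unadjusted p under 0.05 and 15 by fry. Cell cycle genes were higher (33 of 36 up, 34 adjusted over the list alone; adjusted p = 4.85e-30, and adjusted p = 0.0517 with an estimated correlation). So were glycolysis (20 of 25 up, 20 adjusted over the list alone; 1.50e-09, and adjusted p = 0.303 with an estimated correlation) and sterol genes (3 of 24 up, 3 adjusted over the list alone, 7 without CDP-derived replicate 2; 0.00159, and adjusted p = 0.470 with an estimated correlation). Interferon-stimulated genes were lower (26 of 35 down, 32 adjusted over the list alone; 4.88e-11, and adjusted p = 0.303 with an estimated correlation), as was the pDC identity list (16 of 34 down and 2 up, 21 and 4 adjusted over the list alone; 3.72e-05, and adjusted p = 0.0777 with an estimated correlation). Erythroid (9 of 13 down, 9 adjusted over the list alone; 1.39e-06) and immediate early genes (17 of 27 down and 2 up, 19 and 2 adjusted over the list alone; 1.54e-06) were lower, each with adjusted p = 0.0691 with an estimated correlation. The monocyte list was lower (7 of 17 down and 1 up, 9 and 2 adjusted over the list alone; 0.00135, and adjusted p = 0.0517 with an estimated correlation). Cytotoxicity (8 of 13 down and 3 up, 8 and 3 adjusted over the list alone; 0.00530) and TLR7/9 sensing lists (10 of 20 down and 1 up, 12 and 3 adjusted over the list alone; 0.0182, and 0.0556 without splenic replicate 2) were lower, each with adjusted p = 0.0691 with an estimated correlation. Irf7 was at 391 ± 54.9 against 1813 ± 104 CPM. Lymphoid progenitor (0.307), MHC class II (0.614), B cell (0.843), plasma cell (0.876), cDC (0.913), chemokine receptor (0.929), T and NK cell (0.929) and neutrophil lists (0.930) were not called. For the lymphoid progenitor and B cell lists the mean lay above 0 and the median below.

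The distance of each cultured library to the tissue pDCs asked which progenitor gave cells nearer to those of the tissue. To BM pDCs it was 1.25 ± 0.07 for CDP-derived and 1.08 ± 0.06 for IL7R LP-derived libraries (root mean square log2 difference, n = 3 each), a difference of 0.166 with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give. To splenic pDCs it was 1.28 ± 0.05 and 1.22 ± 0.04, a difference of 0.0601 with an exact two-sided permutation p = 0.2. With the 500 most variable genes this difference was -0.0295 (exact two-sided permutation p = 0.9). The BM and splenic means lay 0.692 apart. This value and the distances to BM pDCs take in the granulocyte and red cell genes of the BM libraries.

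Of the 300 genes called between the cultured groups, 63 were also called between the tissues. Of the 176 genes higher in CDP-derived than IL7R LP-derived pDCs and the 107 genes higher in spleen than BM, 52 were shared (32 of 138 and 62 without splenic replicate 3), where independent lists of these sizes would share 1.44 genes (two-sided Fisher's exact test over 13042 genes, p = 1.04e-70; genes are not independent replicates). Of the 124 and 215 lower genes 9 were shared, with 2.04 for independent lists, and 1 gene moved in each opposite way. These comparisons have no library in common, but both came from 1 fit of all 12 libraries with a shared spread per gene. The sets of calls are therefore not independent. The shared higher genes included Klf4, Plbd1, Rab3il1 and, chosen after their values were seen, Lgals3, the galectin 3 gene (775 against 218 CPM in the cultured and 96.7 against 24.3 CPM in the tissue groups), and Gpr183, an oxysterol receptor gene that positions dendritic cells (145 against 44.3 and 129 against 50.7 CPM). Sema4a, which the rule named for the tissues, stood at 129 against 21.3 CPM in the cultured groups. The shared lower genes included Cd247, whose call between the tissues was lost without splenic replicate 1 (adjusted p = 0.0541).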

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

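All tests of the interferon and cell cycle patterns in this part were chosen only after the results had been seen.

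In IL7R LP-derived replicate 3 the interferon-stimulated list had a median of 34.5 CPM, against 3.88 and 2.27 CPM in replicates 1 and 2, 4.16 to 5.50 CPM in CDP-derived libraries and 26.0 to 36.8 CPM in tissue libraries. All 35 members were higher there than in the mean of the other 2, by a median of 4.35 times. Cells or RNA from the tissue samples, or a swap with one, could raise these genes, but the tissue share they imply was 74.5% (quartiles 55.3% to 122%) over 11 interferon-stimulated genes and 1.05% (-0.295% to 5.83%) over 95 other genes low in the cultures, which excludes it as the cause. Handling stress is not excluded. The immediate early and stress genes had a median ratio of only 1.05 (quartiles 0.846 to 1.52), but 15 of 27 were higher and 5 were at least 2 times higher. Their median level was also highest in this library, at 11.5 CPM against 7.95 and 5.23 CPM in replicates 1 and 2. No biological explanation was tested, because the design has no group that bears on 1 library.

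Cell cycle genes had medians of 32.2, 31.4 and 23.9 CPM in BM libraries and 4.80, 6.13 and 5.96 CPM in splenic libraries. Dividing granulocyte progenitors carried into the BM sort could give this, but across the 3 BM libraries the highest-to-lowest ratio was 1.39 (quartiles 1.23 to 1.51) for the cell cycle genes and 39.2 for Mpo, the myeloperoxidase gene of such progenitors, which excludes them as the cause. Erythroid cells cannot be told apart from dividing pDCs by these libraries, because the globin share had a highest-to-lowest ratio of 1.59 and did not run against the cell cycle genes. Tissue is the only biological factor in this comparison, and the libraries hold no sorted fraction that would separate it from carried-over cells.

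The difference between CDP-derived and IL7R LP-derived pDCs in their change from BM passed limma's camera test, with the preset correlation, for 7 gene lists. It is the comparison of the cultured groups itself, as BM cancels, and mean log2 differences follow with each group's change from BM, CDP first. They were 1.04 for monocyte genes (-1.56 and -2.60, adjusted p = 1.28e-04) and 0.62 for MHC class II (0.52 and -0.10, adjusted p = 1.34e-06). Glycolysis and hypoxia differed by 0.65 (1.77 and 1.12, adjusted p = 3.07e-05) and cDC identity by 0.63 (0.22 and -0.41, adjusted p = 0.00474). Lower in the CDP-derived cells were B cell genes, by -0.99 (0.10 and 1.09, adjusted p = 6.37e-04), interferon-stimulated genes, by -0.79 (-3.05 and -2.26, adjusted p = 8.37e-04), and the cell cycle, by -0.25 (1.11 and 1.36, adjusted p = 0.0146). The difference in interferon-stimulated genes was 0.22 (adjusted p = 0.231) without IL7R LP-derived replicate 3, and that in the cell cycle was not called without replicate 2 of the IL7R LP-derived or the CDP-derived group (adjusted p = 0.458 and 0.0951). In each of these 2 lists edgeR called 0 members between the cultured groups, and with adjustment over the list alone 17 of the 35 interferon-stimulated genes and 0 of the 36 cell cycle genes. Glycolysis and hypoxia had 0 of 25 members called in both ways. Its median was 57.0 CPM in CDP-derived replicate 2, against 161 and 157 CPM in CDP-derived replicates 1 and 3. With an estimated correlation 2 of the 7 passed, monocyte and B cell genes (adjusted p = 0.0324 and 0.0378).

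With 3 against 3 each comparison has 10 splits, too few for a split test at 0.05. The real ones called 300, 322, 1694, 3153, 2168 and 3149 genes in the order of the report, and the others 0 by edgeR. The others mix both groups, whose difference then adds to the spread, so their 0 calls lend no support. At an unadjusted p under 0.05 the highest other splits gave 875, 1848, 1436, 1613, 676 and 1066 genes against 1970, 1318, 3298, 4969, 3573 and 4853 for the real ones. The split with 1848 genes, of splenic and BM libraries, parted 1 same-numbered pair, and the other 3 splits that part all 3 pairs, as the real one does, gave 105 to 238.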

How the results depend on the processing

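Counts of called genes are given here where they moved by over 1.5 times, and the cause was not tested unless stated. For CDP-derived minus IL7R LP-derived pDCs (300) the DESeq2 Wald test called 641 and limma-voom with quality weights 573, and a fit of only the 6 libraries, with fewer degrees of freedom, called 192. An adjusted p under 0.01, stricter by construction, left 126. Leaving out 1 library gave 172 to 312. For splenic minus BM (322) the stricter threshold left 198, and leaving out 1 library gave 230 to 278. For IL7R LP-derived minus BM (1694) limma-voom called 2896, the stricter threshold 885, and leaving out 1 library 1133 to 2022. For CDP-derived minus BM (3153) the 6-library fit called 2003, the stricter threshold 1506, and leaving out 1 library 2104 to 3508. For IL7R LP-derived minus splenic (2168) limma-voom called 3833, the stricter threshold 1341, and leaving out 1 library 1634 to 1861. For CDP-derived minus splenic (3149) limma-voom called 5007, a minimum change of 2-fold 2084, the stricter threshold 1629, and leaving out 1 library 2084 to 2788.

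Same-numbered splenic and BM libraries deviated together, but no label says what the numbers mark. The replicate block called 318 genes in splenic minus BM with all 12 libraries and 817 in a fit of the 6 libraries, which was chosen after seeing the data. Among gene lists the block ended 1 call, that of B cell genes in IL7R LP-derived minus BM pDCs (adjusted p = 0.0501), and 107 results were the same. In the block of the 6 libraries 17 of 18 lists were the same and interferon-stimulated genes were newly called lower (mean log2 fold change -0.36, adjusted p = 8.55e-05), and with an estimated correlation in that fit, which has fewer libraries, camera called 0 lists (1 at an unadjusted p under 0.05; 9 with the preset correlation). Among named genes the block with 12 libraries left 577 results the same, with 23 newly called and 3 lost. In the block of the 6 splenic and BM libraries 77 of 96 were the same and 19 were newly called, among them H2-Aa (log2 fold change 0.63, adjusted p = 0.0263), Cd74 (0.55, adjusted p = 0.0210), Il2rg (0.99, adjusted p = 9.18e-04), Spib (-0.47, adjusted p = 0.0249) and Dntt (-0.65, adjusted p = 0.0131), and not Siglech, Bst2, Tcf4 or Irf8.

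With an estimated correlation the lists called numbered 2, 5, 6, 3, 5 and 0 in the order of the report, against 7, 8, 12, 12, 12 and 10, and by fry 6, 7, 14, 14, 13 and 15. Results that turned, by the direction of the test, were the following. Interferon-stimulated genes in CDP-derived minus IL7R LP-derived pDCs had a mean log2 fold change of 0.22 (adjusted p = 0.231) without IL7R LP-derived replicate 3, against -0.79, and -1.44 to 0.22 over all left-out libraries. T and NK cell genes in IL7R LP-derived minus BM pDCs (-0.25) were called lower by fry (adjusted p = 0.0382), whereas camera gave the direction up (adjusted p = 0.820). Monocyte genes in CDP-derived minus BM pDCs had a mean of -0.0595 (adjusted p = 0.683, direction up) with a filter of 5 CPM in 3 libraries, which tests fewer genes. The distance difference to splenic pDCs was -0.0295 (exact two-sided permutation p = 0.9) with the 500 most variable genes and 0.0323 to 0.0855 over left-out libraries, and that to BM pDCs was 0.137 to 0.204.

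Of the list results with 1 library left out 607 were the same, 14 were newly called, 26 were lost and 1 turned in the direction of the test. The mean of the B cell list in splenic minus BM pDCs, called lower at -0.34, was above 0 in 5 of 6 such fits (0.0708 to 0.132) and -0.19 without splenic replicate 2, with the test's direction down and no call in each. These fits also tested more genes, so this shift cannot be laid to the missing library alone. Of the named-gene results 3409 were the same, 29 were newly called and 180 were lost. DESeq2's size factors left 602 of the named-gene results the same, no filter 591 and scaling by total counts 589. Depth limits genes with 0 to 3 counts in a group, for which only a bound on the fold can be given.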

Other observations

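The test of the correlation over all 100 pairs of splits was planned before its result, and the other tests in this part, that over 40 pairs included, were chosen only after the results had been seen.

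Genes named here were chosen after their values were seen. Among the genes higher both in CDP-derived than in IL7R LP-derived pDCs and in splenic than in BM pDCs were Pros1, which encodes the anticoagulant protein S (log2 fold changes 2.76 and 1.89), and Fcgrt, the neonatal Fc receptor gene (2.51 and 1.10). Among the shared lower genes, Lck, the T cell kinase gene, had log2 fold changes of -1.58 and -1.88, and its call between the cultured groups was lost without IL7R LP-derived replicate 1 or CDP-derived replicate 3 (adjusted p at most 0.0573).

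A hypothesis of this re-analysis is that the spleen holds more pDCs resembling CDP-derived ones than the BM does. It may follow from the 52 genes higher in both comparisons, where independent lists would share 1.44, though both sets of calls came from 1 fit and are not independent. It may also follow from a correlation of log2 fold changes across genes of 0.204 (0.240 without the cell cycle, granule, erythroid and interferon-stimulated lists). As large an absolute correlation arose in 3 of 100 pairs of splits, with 0.259 as the highest other, under the limit of 5 set before, but same-numbered splenic and BM libraries deviate together and these splits are not alike in how many such pairs they part. Among the 40 pairs that part all 3 same-numbered pairs, as the real one does, it was 1 of 40, the fewest possible, with 0.192 as the highest other, and genes are not independent replicates. Leaving out 1 library left 32 to 47 shared higher genes, but over whole profiles CDP-derived libraries lay no nearer to splenic (1.28) than to BM pDCs (1.25), and IL7R LP-derived ones lay nearer to both (1.22 and 1.08), and bulk libraries do not separate a larger share of such cells from a rise in all pDCs, which single-cell profiles of both tissues would test.

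Contaminating cells could also raise the same genes in both comparisons. Neutrophils are excluded as the cause, since S100a8 and S100a9 reached at most 0.0711 CPM in the CDP-derived and splenic groups, against a median rise of 18.6 and 13.6 CPM for the shared genes. Monocytes stay open: 2 of 17 tested members of their list, Cd14 and Cx3cr1, were higher in both, and the list was called higher in both (adjusted p = 0.0324 and 0.0298 with an estimated correlation), but Lyz2, an abundant gene of monocytes and also of granulocytes, rose by 5.86 CPM between the cultured groups and fell by 80.5 CPM, to 14.8 CPM, from BM to spleen, where BM also held neutrophil genes. With the replicate number as a block in the 6 splenic and BM libraries, camera with an estimated correlation called 0 lists (lowest adjusted p = 0.359). The tissue call of the monocyte list was thus lost in that smaller fit. The call of Cx3cr1 between the cultured groups was lost without any 1 of 5 libraries, all but CDP-derived replicate 1 (adjusted p = 0.0530 to 0.104), and that of Cd14 between the tissues without any 1 of 8: splenic replicates 1 and 3, BM 2 and 3, IL7R LP-derived 1 and 2 or CDP-derived 2 and 3 (adjusted p at most 0.164). Conventional dendritic cells cannot be told apart from such pDCs, since 2 of 24 tested members of the cDC list, Zbtb46 and Klf4, were higher in both (Zbtb46 was not called between the tissues without splenic replicate 2 or BM replicate 3, adjusted p = 0.0584 and 0.0805), whereas other members did not rise in this way: Id2 changed by 0.658 and -1.60 CPM, Batf3 by -0.696 and 0.241, Xcr1 by 0.150 and -0.152 and Ccr7 by -10.9 and 2.18.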
